A study of Mus musculus with 3 samples.

How the data were processed

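The samples were 3 sequencing libraries from mouse embryonic stem cells of strain C57BL/6, per the labels: H3K4me3 chromatin from wild-type (floxed) cells, H3K4me3 chromatin from knockout cells, and wild-type input DNA. Groups came from the labels, with 1 library per group. Per the labels' protocols, cells were kept on irradiated fibroblast feeders with leukemia inhibitory factor and moved to gelatin for chromatin immunoprecipitation, an antibody against trimethylated lysine 4 of histone H3 was used, and libraries were PCR-amplified and sequenced on a Genome Analyzer. Feeder cells left in a culture would add reads that were not separated here.

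The authors deposited mapped read positions for each library and an island list for each H3K4me3 library. Bowtie and SICER are named, with build mm9, per the submitters' processing notes. Versions and options are not given in the sources used here. Each deposited read is a single 36-bp interval, with repeated positions kept. The deposited islands start on a grid of 200 bp and carry no score, count or p-value, and the control, gap and threshold used to call them are not given in the sources used here. All values in the report were counted from these positions.

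Reads were reduced to 1 per position and strand, and each was moved 75 bp toward the centre of its fragment. In regions with islands in both lists, plus- and minus-strand read starts were most often 90 bp apart in wild type and 95 bp in knockout, so the shift exceeded the middle of that distance. Counts without any shift were an alternative. Overlapping islands of both lists were merged into 42221 union regions. Those on the 19 autosomes and X with at least 50 reads in both H3K4me3 libraries together were compared, 27810 in all. The libraries were scaled by the median ratio over these regions, which was 1.02 knockout reads per wild-type read, against 0.898 for total nonredundant reads and 0.869 for background reads. A region was called when its scaled ratio was at least 2 or at most 0.5 and its exact 95% conditional binomial (Clopper-Pearson) interval excluded 1. Shares of reads and of islands have exact binomial intervals, and medians have intervals from the binomial order of their values. PCR copies are not independent molecules, so all intervals cover counting error only, and they do not allow for the number of regions compared.

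Background reads lay at least 10 kb from any union region and numbered 8755353 in wild type, 7611305 in knockout and 5848877 in input. The input was scaled to each H3K4me3 library on these reads. For segments, reads more than 1 kb from islands were counted in 500-kb bins with at least 200 wild-type reads (5083 bins). The log2 ratio of knockout to wild type was freed of its linear trend with the log2 ratio of wild type to input, each count in a ratio to input raised by a pseudocount of 1, and cut by least-squares segmentation. Segments of at least 10 bins with a mean of at least 0.1 from 0 were called. Wild-type reads behind each region set the precision: at 50 reads in both libraries together a 2-fold change is near the limit of detection.

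The named regions were set by rule before the data were examined: the 12 regions with the highest lower bound and the 12 with the lowest upper bound of the ratio's interval. For islands in a single list the rule took the 3 with the highest score. As the lists hold no score, the 3 widest were taken.

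On simulated counts for the comparison of knockout with wild type (27945 regions meeting the minimum, 197 of them among the 200 made to change), calls recovered 100% of regions made 4-fold higher, 94.1% of those made 3-fold higher and 32.3% of those made 2-fold higher (10 of 31). For regions made lower the shares were 100%, 94.6% and 55.3% (21 of 38), so in this run 2-fold changes were found more often downward than upward. Of 27748 unchanged regions, 62 were called higher and 54 lower. Segments raised in simulated background were found at their simulated ends in all 3 cases.

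Promoter windows, the 24 gene lists fixed beforehand and reads over Kdm5a were planned only if genes could be placed. The gene table at hand was of another assembly (GRCm38.p6) and no conversion between builds was made, so these results were not made and no gene is named for a region. Alternatives covered repeated reads, scaling, input subtraction, read shift, count minimum, depth, island overlap and, added after the data were seen, island width, chromosomes 6 and 11, segment background and regions in both lists. Computations used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and pandas 2.3.3, and plots used Matplotlib 3.10.9.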

Results

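Trimethylation of lysine 4 on histone H3 (H3K4me3), a mark found mainly at active gene starts, was mapped by chromatin immunoprecipitation and sequencing in mouse embryonic stem cells. One culture carried intact floxed alleles of Kdm5a, called wild type here. The other lacked the gene. Kdm5a, also known as Rbp2 or Jarid1a, encodes a demethylase that removes methyl groups from this lysine, and the design text asks about histone methylation in its absence. There were 3 libraries, with 1 per group: H3K4me3 from wild-type cells, H3K4me3 from knockout cells, and input DNA from the wild-type cells. No group had a replicate, so no test between genotypes was made, no p-value is given, and each interval covers counting error in these libraries only.

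The wild-type H3K4me3 library held 15441674 mapped reads of 36 bp, of which 14885253 remained with 1 read per position and strand. The knockout H3K4me3 library held 13996965 mapped and 13371824 nonredundant reads, and the input 8282926 and 8043111. Repeated positions made up 3.60% of the wild-type reads, 4.47% of the knockout reads and 2.90% of the input reads. Coordinates are those of build mm9, counted from 1. No mm9 gene annotation was used, so regions are named by position, and the targeted gene's own reads, which would check the genotype labels, were not analysed here.

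H3K4me3 was enriched at the deposited islands in both genotypes, and the enrichment was higher in the knockout library. In the union of both island lists, which covered 82297400 bp, lay 16.9% of the wild-type reads (exact 95% interval 16.9 to 17.0), 20.1% of the knockout reads (20.1 to 20.2) and 4.52% of the input reads (4.50 to 4.53). These shares were 3.75 times the input share in wild type and 4.46 times in knockout. In regions with islands in both lists the shares were 12.3% in wild type, 16.1% in knockout and 2.24% in input, or 5.49 and 7.18 times the input. The difference between the genotypes exceeded the counting error, but with 1 library each it cannot be separated from variation between immunoprecipitations.

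Around the strongest point of 14167 regions with islands in both lists, on autosomes other than 6 and 11, the knockout library rose higher than the wild-type library. Within 500 bp of that point, wild-type reads were 13.7 times the scaled input and knockout reads 19.1 times. After removal of scaled input, the knockout excess was 1.42 times the wild-type excess. At 1 to 2.5 kb from that point the densities were 1.77 and 1.80 times the scaled input, and the excess ratio was 1.04. The difference between the libraries was largest at the centres of the regions. In bins of 100 bp the excess ratio fell from 1.24 at -1100 bp to 0.89 at -2500 bp. On the other side it fell from 1.22 at 1100 bp to 0.93 at 2400 bp. The flank value of 1.04 thus averages a higher inner and a lower outer part.

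**Figure D1:**
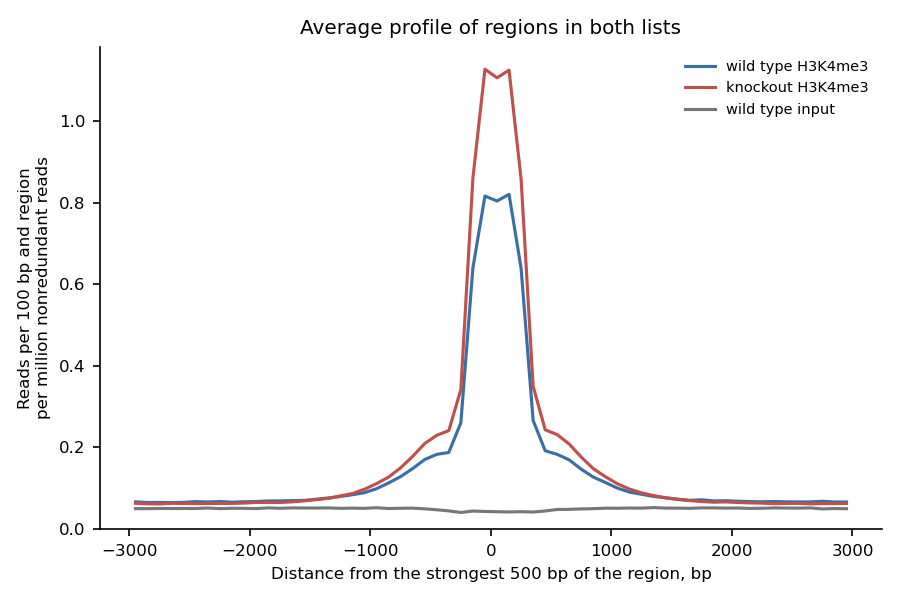
Average reads in each 100 bp of a region, scaled to library size (vertical axis), against the distance in bp from the strongest 500 bp of each region (horizontal axis), over 14167 regions with islands in both lists. The knockout H3K4me3 line (red) stands above the wild-type H3K4me3 line (blue) at the centre, both converge in the flanks, and the wild-type input (grey) stays flat.

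The authors' island lists differed between genotypes in number, width and place. The wild-type list held 33824 islands covering 63454000 bp, with a median width of 1600 bp. The knockout list held 27797 islands covering 45597400 bp, with a median width of 1400 bp. Of the wild-type islands, 18696 (55.3%, exact 95% interval 54.7 to 55.8) overlapped a knockout island by at least 1 bp, and 18814 of the knockout islands (67.7%, 67.1 to 68.2) overlapped a wild-type island. Among 17050 pairs in which 1 island of each list met only the other, the knockout island was narrower in 7930, wider in 6334 and equal in 2786. The mean widths of these pairs were 1868 bp in wild type and 1715 bp in knockout, but the median width was 1600 bp in both, and on chromosome 6 the knockout island was wider in 463 pairs and narrower in 326. The lists were called separately on libraries of different depth and enrichment, so an island missing from a list does not show that the mark was missing.

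Islands found in the knockout list alone were concentrated on chromosomes 6 and 11. The union comprised 18110 regions with islands in both lists, 15128 in the wild-type list alone and 8983 in the knockout list alone. Chromosomes 6 and 11 held 18.0% of the regions in both lists, 11.1% of those in the wild-type list alone and 42.0% of those in the knockout list alone. On chromosome 6 the wild-type list had 1460 islands and the knockout list 2447. On chromosome 11 the numbers were 3673 and 4840. Every other autosome had fewer knockout than wild-type islands, as chromosome 2 with 2868 against 1951, while chromosome X had 376 wild-type and 423 knockout islands. Outside chromosomes 6 and 11, 74.6% of the knockout islands and 53.1% of the wild-type islands were shared. Knockout reads outside the islands were in excess on parts of these chromosomes as well, from 1.13-fold to 1.63-fold by segment.

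The deposited lists hold no score, so the widest island regions of each list alone are given. The widest in the wild-type list alone lay on chromosome 11 from 3049401 to 3100400 and held 10764 wild-type, 9399 knockout and 5675 input reads, the input being high there as well. The next lay on chromosome 1 from 90179401 to 90189200, with 455 wild-type, 324 knockout and 205 input reads, and on chromosome 4 from 136246001 to 136254200, with 194, 92 and 55 reads. The 3 widest in the knockout list alone were each 6400 bp wide and all lay near the start of chromosome 11, at 3275801, 5007801 and 8450801. They held 74, 93 and 86 wild-type reads against 129, 139 and 130 knockout reads. All 3 fell in a segment with excess knockout background, as did the widest of the wild-type list alone, whose ratio to the median region was 0.86.

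The typical region had a slightly higher H3K4me3 level in the knockout library. Over 27810 union regions with at least 50 reads in both H3K4me3 libraries together, the median log2 ratio of knockout to wild type was 0.18 in nonredundant reads scaled to library size (95% interval of the median 0.15 to 0.19). It was 0.22 when the libraries were scaled on background reads, and 0.11 on the library-size scale without chromosomes 6 and 11. Regions with islands in both lists had a median of 0.32, those in the wild-type list alone -0.57 and those in the knockout list alone 0.59. An island in a single list favours a high count in that library, so the single-list medians partly follow from how those regions were chosen. No spike-in fixed an absolute scale, so the changes of single regions are given relative to the median region, where the typical shift is 0.

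The change was not uniform: the ratio of knockout to wild type rose with the signal. Relative to the median region, the octile of regions with the fewest reads (50 to 55 in both libraries together) had a median log2 ratio of -0.52, and the octile with the most (344 or more) had 0.31. Among regions with islands in both lists these medians were -0.18 and 0.31, which are -0.003 and 0.49 on the library-size scale and 0.04 and 0.53 on the background scale, so whether the weak regions were lower depended on the scale and on the regions chosen. The median number of input reads was 7 in the weakest octile and 10 in the strongest. In 2-kb tiles set without the island lists, on autosomes other than 6 and 11 and on the background scale, the log2 ratio was -0.06 (95% interval -0.06 to -0.05) in 32820 weak tiles and 0.55 (0.54 to 0.56) in the 1191 strongest. The ratio was lower in weak than in strong places under either choice of regions.

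**Figure D2:**
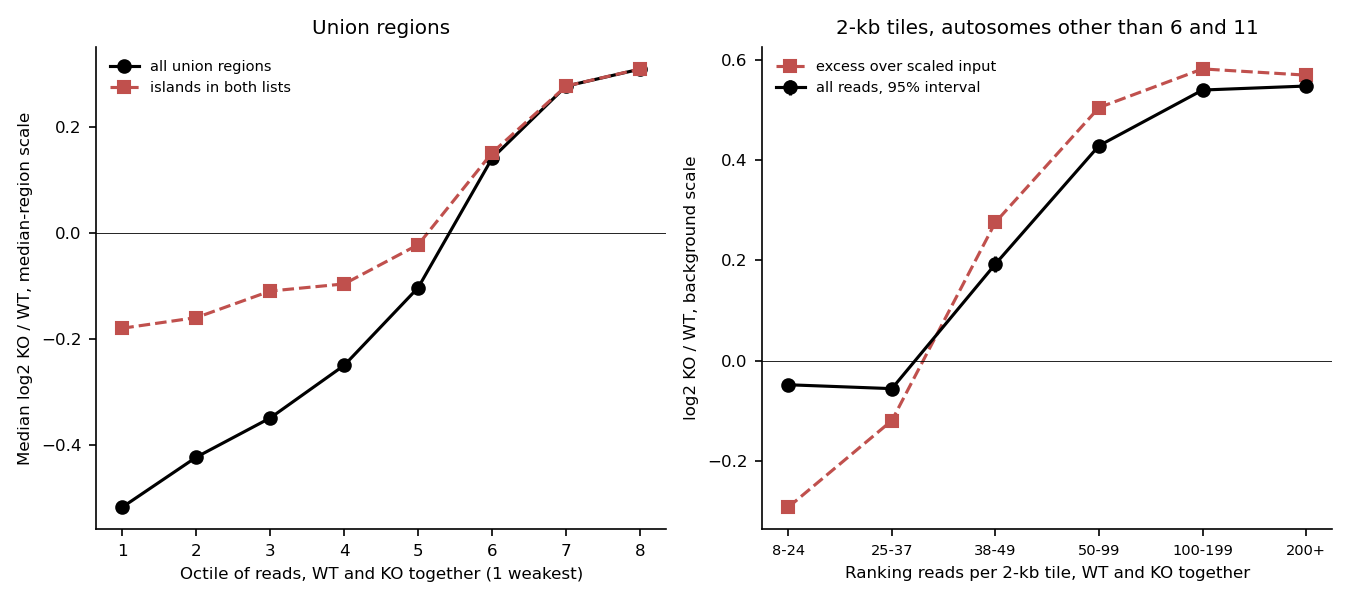
Left, median log2 ratio of knockout to wild-type reads (vertical axis, median region at 0) by octile of reads (horizontal axis) for all union regions (black) and those with islands in both lists (red). Right, log2 ratio on the background scale in 2-kb tiles grouped by ranking reads, for all reads (black, with 95% counting intervals) and for the excess over scaled input (red). The ratio rises from the weak to the strong groups in both panels, from -0.52 to 0.31 in all union regions.

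At least 2-fold changes were few among strong regions and mostly upward there. Of the 27810 regions, 300 were at least 2-fold higher and 1683 at least 2-fold lower in the knockout library with an interval excluding 1, so 15.1% of the changed regions were higher. Counting error alone would give 61.4 higher and 57.4 lower regions if every region held the typical ratio. Those figures take no account of how regions were chosen, as an island in a single list favours a high count in that library. Of the regions higher, 130 had islands in both lists and 170 in the knockout list alone. Of those lower, 1662 lay in the wild-type list alone and 21 in both. Among regions in both lists, counting error alone would give 14.8 higher and 13.7 lower. The total of 21 lower hides a difference by signal. In the octile of 50 to 55 reads 0 were lower against 3.5 expected. In the octile of 95 to 134 reads 10 were lower against 0.61 expected, so those exceed counting error. Among the 7438 regions with at least 200 reads, 70 were higher and 3 lower, where counting error alone would give fewer than 1 of either. That expectation sets every region at the typical ratio, whereas these strong regions had a median log2 ratio of 0.29 on that scale. Their split therefore includes the rise of the ratio with signal.

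The balance of higher and lower regions depended on the scale between the libraries. Scaling on total nonredundant reads gave 721 higher and 820 lower regions (46.8% higher), and scaling on background reads gave 914 higher and 680 lower (57.3% higher). The count of higher regions also rested on chromosomes 6 and 11, which held 202 of the 300. Without them 98 were higher and 1576 lower, and after each region was divided by the background ratio of its segment 121 were higher and 1909 lower. That division lowers the median region, and with the median set back to 1 the counts were 179 and 1462. Among regions with at least 200 reads, 54 of the 70 higher regions were on chromosomes 6 and 11. The division by the segment's background, with the scale kept, left 18 higher in all, 2 of them on these chromosomes. Among regions with islands in both lists, 81 of the 130 higher regions were on chromosomes 6 and 11, and the division changed the 130 higher and 21 lower to 52 and 33.

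Region by region, the strongest rise by the interval's lower bound was on chromosome 19 from 45815401 to 45818000, which went from 66 wild-type to 235 knockout reads with 5 input reads (ratio to the median region 3.51, 95% interval 2.66 to 4.68). A region on chromosome 2 from 70313201 to 70316200 went from 78 to 225 reads (2.84, 2.19 to 3.72), and another from 13495201 to 13497400 from 83 to 213 reads (2.53, 1.95 to 3.30). Chromosome 9 from 118386601 to 118390200 went from 103 to 267 reads (2.55, 2.03 to 3.24), and chromosome 7 from 67147601 to 67150200 from 164 to 391 reads (2.35, 1.95 to 2.84). On chromosome 11, the region from 22871801 to 22875000 went from 159 to 385 reads (2.38, 1.98 to 2.89) and lay outside the segments with excess knockout background.

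The other 6 of the 12 highest regions lay inside those segments. On chromosome 11, the region from 84336201 to 84340800 went from 65 to 194 reads, a ratio of 2.94 that became 2.45 after division by its segment's background ratio with the scale kept. On the same chromosome, the regions from 4747801 to 4750000 (153 to 409 reads, ratio 2.63) and from 6445201 to 6448600 (108 to 268 reads, ratio 2.44) fell to ratios of 1.62 and 1.501 after that division. On chromosome 6, the region from 119985801 to 119990000 had 236 and 582 reads and a ratio of 2.43, which fell to 1.77. The region of chromosome 6 from 137117601 to 137118400 (18 to 62 reads) and that of chromosome 11 from 8612401 to 8616200 (24 to 76 reads) were in the knockout list alone and rest on few wild-type reads. Their ratios of 3.39 and 3.12 became 2.47 and 1.92 after the division, so 4 of these 6 regions fell below 2-fold.

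Of the 12 lowest regions, 11 had an island in the wild-type list alone and low counts. The lowest by the upper bound lay on chromosome 3 from 89582601 to 89586400, with 67 wild-type, 13 knockout and 15 input reads (ratio 0.19, 95% interval 0.10 to 0.35). Chromosome 1 from 122070801 to 122074200 went from 60 to 12 reads (0.20, 0.10 to 0.37), and chromosome 8 from 74767801 to 74770000 from 43 to 8 reads (0.18, 0.07 to 0.39). The exception with islands in both lists was on chromosome 11 from 11936401 to 11938200, which went from 142 to 40 reads with 5 input reads (0.28, 0.19 to 0.40). It was 18.97 times the scaled input in wild type and 6.15 times in knockout, against 2.98 and 0.67 times for the lowest region. The remaining 8 lay on chromosomes 1, 2, 3, 5, 7, 14 and 15, and the 12 ratios ranged from 0.18 to 0.28. With scaled input subtracted, and each subtracted count kept at 1 read or more, the 11 regions in the wild-type list alone had ratios from 0.021 to 0.077. In most of them knockout reads lay below the scaled input, so that floor set the ratio and no fold was measured. The ratio of the region on chromosome 11 from 8612401 rose from 3.12 to 34.4, with wild-type reads only 1.07 times the scaled input. The sizes of the changes in regions near the input level are therefore not fixed. All 24 named regions kept their call with all mapped reads. They also kept it with both other scales, but these raise every ratio alike, to at most 0.32 in the lower regions, so that outcome was fixed.

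**Figure D3:**
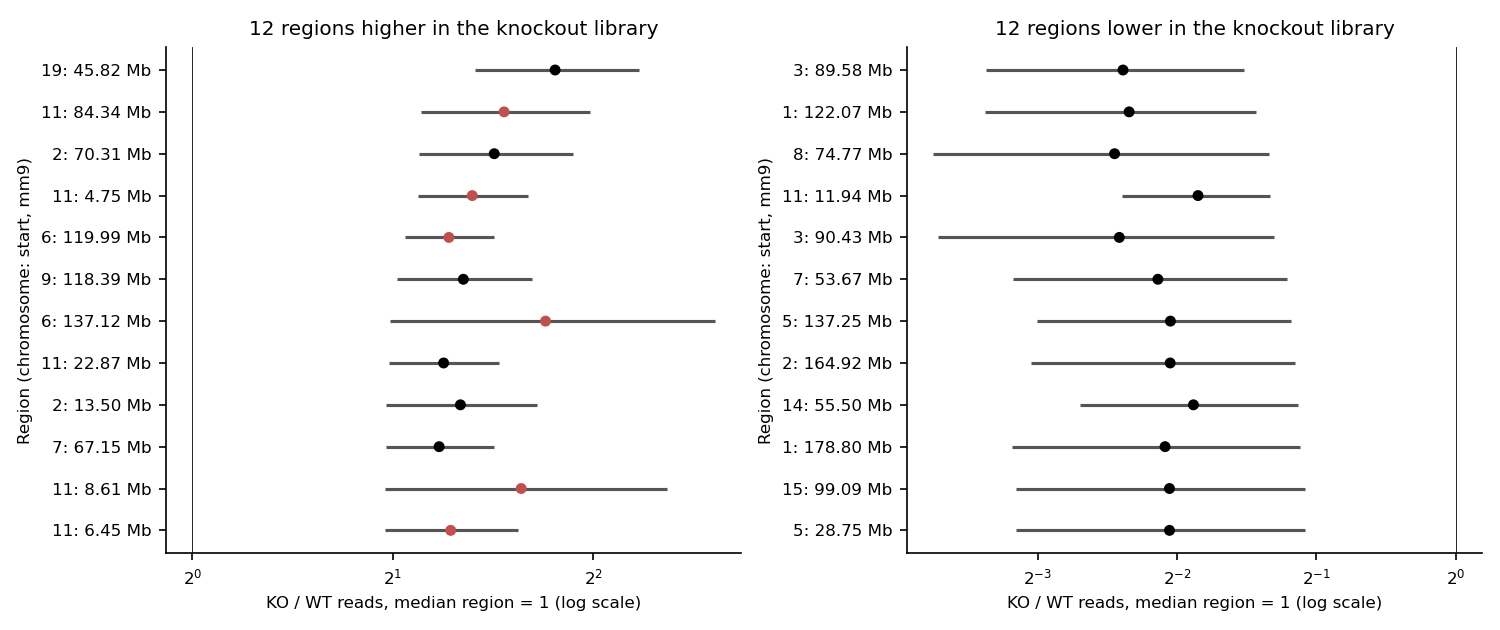
Ratio of knockout to wild-type reads (horizontal axis, log scale, median region at 1) with its 95% counting interval for the 12 regions with the highest lower bound (left) and the 12 with the lowest upper bound (right), named by chromosome and start. Red points lie in segments with excess knockout background. The 12 higher ratios range from 2.35 to 3.51 and the 12 lower from 0.18 to 0.28.

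Chromosomes 6 and 11 also carried more knockout reads outside the islands. At least 10 kb from any island, the knockout to wild-type ratio relative to the median autosome was 1.23 on chromosome 6 (95% interval 1.23 to 1.24) and 1.14 on chromosome 11 (1.13 to 1.14). On the other 17 autosomes it ranged from 0.963 on chromosome 1 to 1.03 on chromosome 8, and it was 1.04 on chromosome X. In 500-kb bins the excess formed 4 segments, 2 on each chromosome, and from 9500001 to 37000000 on chromosome 11 the ratio was 0.966. Against the input, chromosome 6 stood at 0.958 in wild type and 1.17 in knockout, and chromosome 11 at 1.02 and 1.16. Among the union regions compared, the median log2 ratio was 0.35 on chromosome 6, 0.16 on chromosome 11 and 0.27 on chromosome X, against -0.07 over the other autosomes. Regional differences on chromosomes 6 and 11 therefore include this difference in background.

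**Figure D4:**
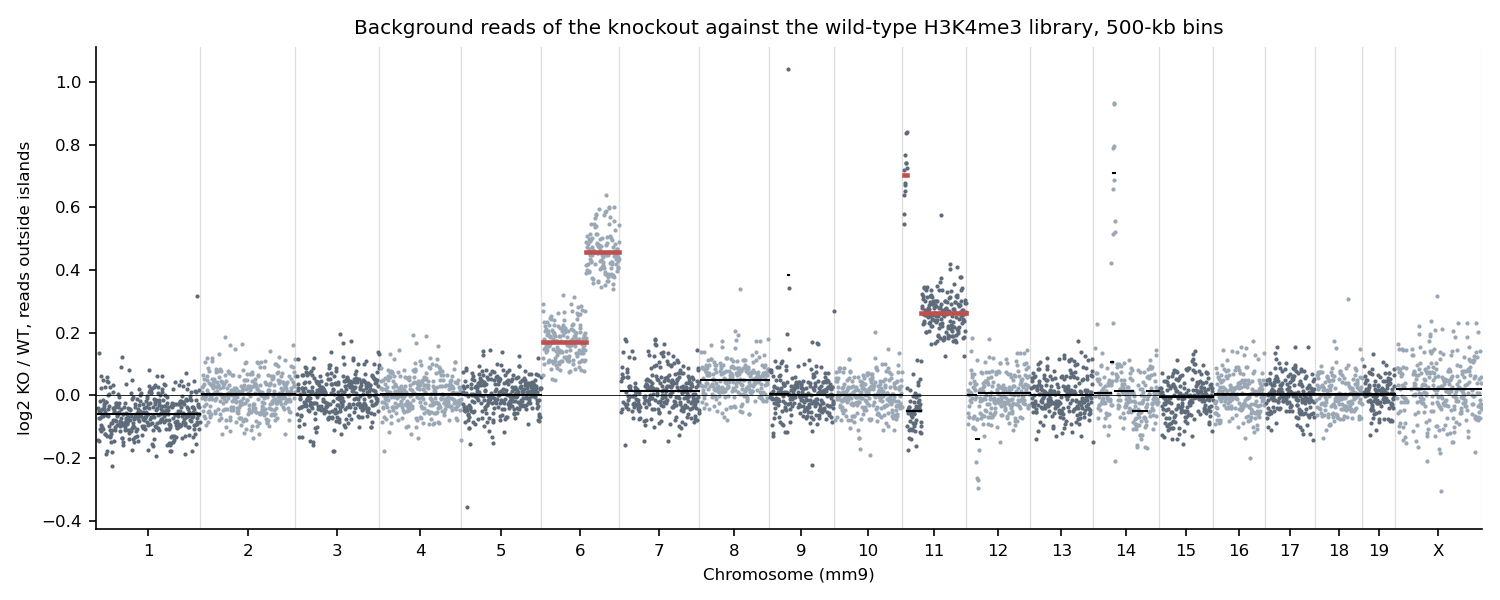
Log2 ratio of knockout to wild-type H3K4me3 reads outside the islands (vertical axis, autosomal median near 0, trend with the ratio of wild type to input removed) in 500-kb bins along the chromosomes of mm9 (horizontal axis). Lines are segment means, red where called. The called segments on chromosomes 6 and 11 have means from 0.17 to 0.70, and the other segments of at least 10 bins lie between -0.06 and 0.05.

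**Figure D5:**
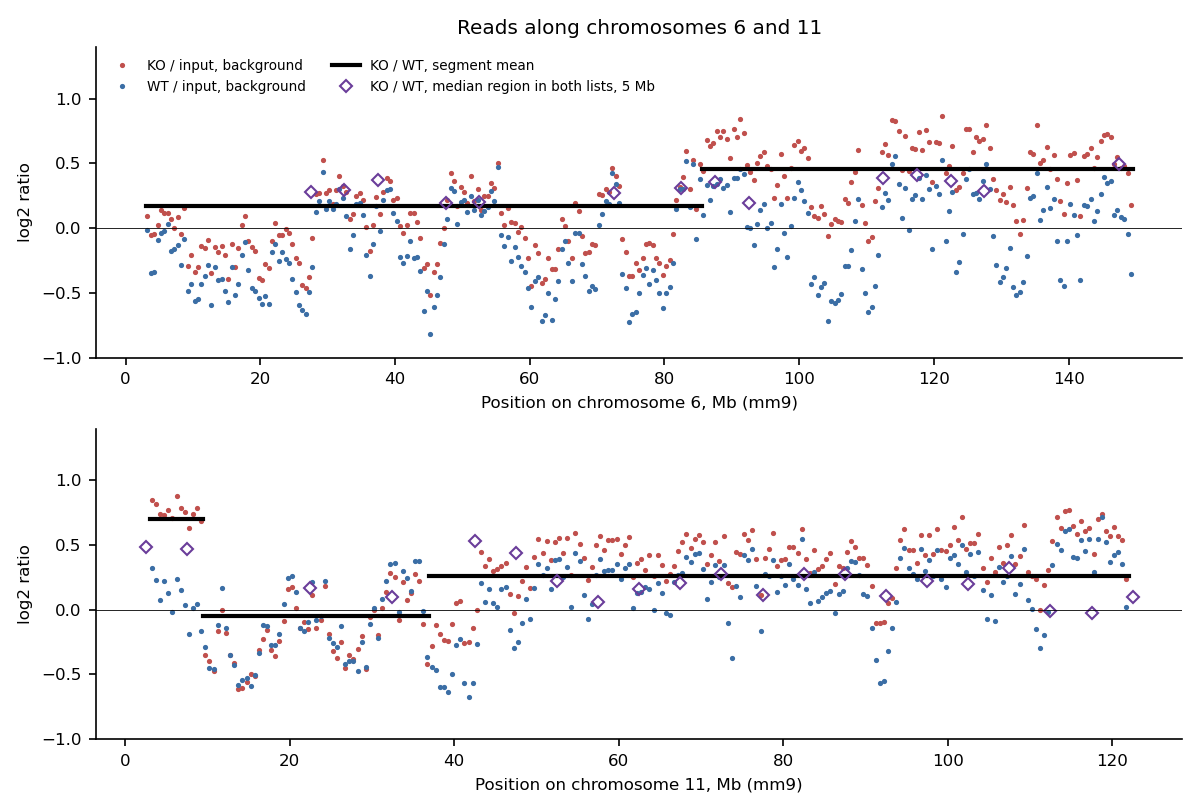
Log2 ratio (vertical axis) of background reads of the knockout (red) and wild-type (blue) H3K4me3 libraries to the input in 500-kb bins along chromosomes 6 and 11 of mm9 (horizontal axis, Mb), with the segment means of knockout over wild type (black) and the median ratio of regions in both lists per 5 Mb (diamonds). The knockout points stand above the wild-type points in the 4 raised segments, most at the start of chromosome 11, and overlap them from 9500001 to 37000000 on chromosome 11.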

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

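The tests of scaling, of copy loss in wild type and of islands of the wild-type list were chosen after the excess was seen, and the others before their results were seen. Reads outside the islands, which the comparison of H3K4me3 regions does not use, showed blocks of knockout reads in excess of the wild-type library. On chromosome 6 the knockout to wild-type ratio was 1.13 from 3000001 to 85500000 and 1.37 from 85500001 to 149500000. On chromosome 11 it was 1.63 from 3000001 to 9500000, 0.966 from 9500001 to 37000000 and 1.20 from 37000001 to 122000000. The knockout library also exceeded the input in 3 of the 4 raised segments, but in the proximal segment of chromosome 6 it was level with it (log2 0.003). The positions are resolved only to 500 kb, and the 4 raised segments span 238 Mb. In the segment at the start of chromosome 11 the wild-type list had 257 islands and the knockout list 831, and in the distal segment of chromosome 6 they had 872 and 1872. The lists differed less in the distal segment of chromosome 11 (3177 and 3840) and in the proximal segment of chromosome 6 (587 and 574).

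Several technical causes are argued against. A scaling difference moves all chromosomes alike, yet background at least 10 kb from islands was not alike across autosomes. Relative to the median autosome, the knockout to wild-type ratio was 1.23 on chromosome 6 and 1.14 on chromosome 11. On the other 17 autosomes it ranged from 0.963 to 1.03. The lowest raised segment stood 0.12 (log2) above the highest segment of at least 10 bins on other autosomes (standard error 0.0056). Segments were called raised at 0.1 or more, so the call fixed the sign of that gap, and the gap adds no support. Shorter stretches reached 0.71 over 9 bins on chromosome 14 and 0.38 over 4 bins on chromosome 9. Spread of H3K4me3 signal from islands would fade with distance, yet the log2 excess at least 50 kb from any island was 1.05 times that at 10 kb or more in the 3 segments with such reads (the start of chromosome 11 had too few, and at least 10 kb from islands its ratio was 1.75). Bins of other autosomes matched on island density and on wild type over input had a median log2 ratio of -0.019, against 0.25 in the raised bins, so composition bias does not account for them, though at the start of chromosome 11 the match was loose (18 against 24 islands per bin). Copies lost from the wild-type culture were tested by wild type over input, which cannot decide the question. The input also came from wild-type cells, and a loss shared by both would leave that ratio unchanged. In the 3 raised segments other than the proximal one of chromosome 6, the excess was added back to wild type over input. The result lay at least 0.30 (log2) above the highest segment of at least 10 bins elsewhere on the autosomes. In the proximal segment of chromosome 6 wild type over input was -0.18, inside the range of other autosomal segments, which reached -0.37. Copies lost from the wild-type culture therefore stay open in every raised segment.

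A candidate explanation is extra copies in part or all of the knockout culture, under which island reads should rise as much as background reads. Over islands in both lists, against islands of like wild-type signal elsewhere, the island rise differed from the background rise by -0.14 (log2) overall and by -0.28 at the start of chromosome 11, past the bound of 0.2 set for that test. In those with at least 100 wild-type reads the difference there was -0.11, with a standard error of 0.053. The bound of 0.2 took no account of the choice of islands: islands in both lists were chosen partly on the knockout library, which favours weak islands with high knockout counts among those used for comparison. In islands of the wild-type list, chosen without the knockout library, the rise was 0.18, 0.45, 0.70 and 0.22 in the 4 segments against background rises of 0.17, 0.46, 0.70 and 0.26, and the largest difference was -0.041. In those with at least 100 wild-type reads it was -0.056, at the start of chromosome 11. Lost wild-type copies would give the same match, so gain in knockout and loss in wild type are left undecided in every raised segment. With 1 culture of each genotype, the genotype and a culture's own history cannot be separated, and no input from the knockout cells was analysed here.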

How the results depend on the processing

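Alternatives on island width, chromosomes, segment background and regions in both lists were chosen after seeing the data. Higher and lower regions (300 and 1683) became 721 and 820 scaled on total reads, 914 and 680 scaled on background, 689 and 3780 with scaled input subtracted, 1577 and 5932 with at least 20 reads, 70 and 3 with at least 200, and 130 and 21 for regions in both lists. Higher regions numbered 121 after division by the segment's background, 179 with the median then set back to 1, and 98 without chromosomes 6 and 11. With input subtracted, each count was kept at 1 read or more and the intervals came from the unsubtracted counts. The counts of higher and lower regions stayed within 1.5 times with all reads, without shift, with wild type thinned and with islands of at least 1000 bp. The typical log2 level (0.18) was 0.22 on background, 0.24 with input subtracted, 0.32 in both lists and 0.11 without chromosomes 6 and 11. Shared wild-type and knockout islands (55.3% and 67.7%) were 43.8% and 53.2% with reciprocal overlap of 0.5, 49.8% and 65.5% from 1000 bp, and 53.1% and 74.6% without chromosomes 6 and 11. Reads in islands (16.9% wild type, 20.1% knockout, 4.52% input) were 17.2% and 20.9% with all reads, 16.8% and 20.01% without shift, and 12.3%, 16.1% and 2.24% in both lists. Background ratios of chromosomes 6, 11 and X stayed within their intervals with all reads. Of 24 named regions, 4 lost the 2-fold call after division by the segment's background, and 3 with the median then set back to 1. Scaling shifts, chosen regions and weak counts show in these values by construction, and the cause was not tested otherwise. Alternatives on island scores were not run, as the lists hold none, and those on promoters, gene lists and Kdm5a were not run, as genes were not placed. No paired analysis was possible because each group has 1 library. At 50 reads a 2-fold change is near the limit of detection.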

Other observations

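The tests of strong tiles alone, of X copies and of X enrichment were chosen after the results were seen, and the others before, except that the ranking of tiles on part of the reads was added after tiles ranked on all reads had been measured. Reads on chromosome Y were present in all libraries: 18581 in wild type, 17048 in knockout and 13569 in input. Along 9 bins of chromosome 14 from 38000001 to 42500000, too few to be called, background reads stood at 1.64 times wild type in the knockout library, with log2 ratios to input of 0.41 in knockout and -0.34 in wild type. This stretch was singled out after its values were seen. Only a deletion of all copies in all cells, with no feeder reads left, would leave a stretch without reads. Among stretches of at least 1000 bp without knockout reads, the most wild-type and input reads in any was 39. Among those without wild-type reads the most knockout and input reads was 35, so no such deletion stood out at this depth. A short deletion would hold fewer reads than these and could not be seen. The scan therefore says nothing on whether the targeted gene was deleted.

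The rise of the knockout to wild-type ratio with signal was weighed against choices of regions and against the immunoprecipitation. In 2-kb tiles ranked on a random part of the reads and measured on the rest, with no island calling, the strongest tiles exceeded the weak ones by 0.60 (log2), so the choice of regions is not the whole cause. Among weak tiles the ratio differed by -0.045 between the highest and lowest input groups, too little for an effect that follows the input count to explain the 0.60. The input count measures open chromatin and composition only indirectly, and the weak tiles themselves stood at -0.06, so these causes are not excluded. A larger immunoprecipitated share in the knockout library predicts 1 multiple of the wild-type excess everywhere. The log2 multiple of weak tiles lay at -0.69 from that of the strongest, which argues against it as the whole cause. Among tiles of at least 50 ranking reads the log2 multiples ranged over 0.077, and the multiples were 1.42, 1.496 and 1.484. That cut was set after the results were seen, and the next group, of 38 to 49 ranking reads, had a multiple of 1.21. A larger share may therefore underlie the tiles of at least 50 ranking reads, with weaker places left open. An effect of the genotype was not tested apart from this.

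X-linked regions in both lists had a median log2 ratio of 0.26 (95% interval 0.21 to 0.31) against 0.13 (0.12 to 0.13) on autosomes other than 6 and 11. Against autosomal regions of the same wild-type read number the X regions stood 0.26 higher, so a mix of read numbers does not account for it, but the 42 X regions with at least 100 wild-type reads stood at -0.095, so the rise lay in weaker X regions. Background density on X was 0.321 of that on autosomes in wild type, so an X region of a given read number is more enriched, and once wild-type reads were divided by the chromosome's background density the difference was 0.039. The higher ratio of weaker X regions may therefore be part of the rise with signal. More X copies in the knockout culture stay open: the ratio of X regions to autosomal regions exceeded that of X background by 0.075, within the bound set for that test, but against autosomal regions of the same read number the excess over background was 0.20 in all X regions, past it, and -0.16 in the 42 strong ones.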
